A study of Mus musculus with 12 samples.

How the data were processed

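Gene expression was measured in the jejunum of male mice of 2 genotypes, wild type and IAP knockout. IAP is intestinal alkaline phosphatase and the knockout lacks Akp3, the gene for its duodenal form. Each genotype received, per the labels, either vehicle (5 g/L carboxymethylcellulose) or IIAEK, a peptide of isoleucine, isoleucine, alanine, glutamic acid and lysine, at 600 mg/kg body weight once a day by mouth from 7 weeks of age. The jejunum was collected after 8 h of fasting, and total RNA from 3 mice per group was hybridised, 1 mouse per array. A source field of the IIAEK samples gives the treatment in weeks, whereas the titles and the protocol give 14 days, and 14 days is used here.

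The authors labelled the RNA with Cy3 and hybridised it to Agilent 8x60K mouse arrays. Per the file headers, the arrays were read with an Agilent scanner and Feature Extraction 10.7.3.1, and each deposited array file holds the processed signal as an intensity that is subtracted for background and detrended within the array but not scaled between arrays. The same deposited files give the median intensity of each spot and of its local background. The deposited value table is in log2 units. Its values follow the log2 processed signal after scaling to the 75th percentile of the array and centring of each probe on its median over the 12 arrays, with correlations of at least 0.9997 in every array; the scaling and centring were found from the values and are not stated. The arrays lay on 2 slides that were also 2 scans. Slide 1 held replicate 1 of both wild-type groups and replicates 1 and 2 of both knockout groups, and slide 2 held the other arrays.

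The array holds 56605 probes other than controls, on 59305 spots. Gene symbols were taken from a table of RefSeq accessions and symbols, which named 32994 probes and 22911 symbols, and the other 23611 probes were kept under their own names. Positions for tests along chromosomes came from the same table, which is on assembly GRCm38.p6, whereas the array design is annotated on mm9; the table was used only for names, chromosomes and neighbourhood, and 23 genes placed on alternate loci were left out of the tests of position. Spots that Feature Extraction marked as non-uniform outliers were removed, 0 to 4 per array. No spot was saturated on any array. The processed signal was taken as log2, spots of a probe were averaged, and the 75th percentile of the array was subtracted, so that a level of 0 is the 75th percentile. Among probes with the same symbol the brightest over all arrays stood for the gene. A gene was tested when its probe was well above background on all 3 arrays of at least 1 group, which left 27565 genes, 15812 with a symbol and 11753 unnamed probes. Where every array of a group lay below background, the smallest fold that the detection limit allows is given as "at least".

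The 4 group means were fitted together over the 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances on 8 residual and 3.37 prior degrees of freedom. From this fit came the 7 comparisons, all two-sided: IIAEK against vehicle in each genotype, knockout against wild type on each treatment, the interaction, and the averages of treatment and genotype effects. P-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, with a threshold of 0.05. Standard errors (SE) are those of limma, and standard deviations (SD) are over the 3 arrays of a group. In 44 lists of genes for pathways, cell types and tissues near the gut, fixed before the data were examined together with the tests, the rule for named genes and the alternatives not marked as later, 42 were tested as lists, and the other 2, genes of the sex chromosomes and genes near Akp3, served the check of sex and the tests of position. The 42 were tested with camera from limma at its preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated from the data. A list is described as higher or lower where the camera test at the preset correlation passed 0.05. Its value is the median log2 change of its members. Over the comparisons, other groupings of the same arrays called a median of 11 to 14 of the 42 lists. A call alone is thus weak evidence for a list. With 3 arrays against 3, an exact permutation test of a single value cannot give a p below 0.1.

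Genes were named by a rule. It takes Akp3, Alpi, Alppl2 and Alpl in every comparison; the 10 largest rises and 10 largest falls among genes that passed the threshold without overlap between the arrays of the groups; where fewer than 10 passed, those with the smallest p up to 10 in all, given as not passing; up to 4 members with the smallest p of each list that is described; and, for IIAEK, 10 genes of sterol and peptide handling. Only characterised symbols were taken in the second and the third part, and 8 of the 10 genes of sterol and peptide handling are given; a few other genes that the rule takes are not reported here. Genes named outside it are marked as chosen after their values were seen. For the knockout, the genes within 20 Mb of Akp3 on chromosome 1 were compared with all other named genes by Fisher's exact test, because a targeted locus can carry DNA of the strain in which it was made.

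The number of arrays limits the precision. The fit was tested on simulated arrays with the means and residual spreads of 27555 real genes, with normal noise that was independent between genes, in which 50 genes per comparison and size were changed. At a log2 change of 1, the share recovered lay between 24% (the interaction) and 82% (knockout against wild type over both treatments); at 2 it lay between 80% and 98%, and at 3 between 94% and 100%. Between 4 and 13 unchanged genes were called per comparison. The changed genes of all sizes were changed at once, which eases the adjusted threshold, and no slide structure was simulated. The shares thus overstate the recovery of an isolated change in these arrays. The alternatives were quantile and median scaling, the authors' values, no filter and a filter on all arrays, the mean of a gene's probes, slide as a block, each slide alone, the replicate number as a block, the compared arrays alone, an intensity trend with a robust prior, array weights, leaving out each array in turn, other thresholds, an estimated correlation between genes and a window of 10 Mb. A normexp correction was to use the mean signal of each spot, which the files lack, so a version on median signals with an offset of 50 was added after the data had been seen. Also added then were a fit without the 2 arrays highest in genes of the exocrine pancreas and the alternatives for the chromosome 1 count. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No count of overlap is given between comparisons that share a group, since the shared arrays alone would make them alike.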

Results

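The data are gene expression profiles of the jejunum from 12 male mice, 3 in each of 4 groups: wild type on vehicle, wild type on IIAEK, IAP knockout on vehicle and IAP knockout on IIAEK. IIAEK is a pentapeptide of bovine beta-lactoglobulin that is known for lowering cholesterol in rodents. The design asks whether the jejunum responds to it differently when Akp3 is missing. The 75th percentile of the signal lay between 575 in knockout vehicle replicate 2 and 816 in wild-type IIAEK replicate 2, and 59.99% to 67.1% of spots were well above background. Arrays of the same group correlated with r between 0.978 and 0.992 across genes, and arrays of different groups with r between 0.965 and 0.994, so the groups did not separate over the whole profile. Genes are not independent replicates in these correlations. All levels are log2 values relative to the 75th percentile of the array, and n = 3 arrays per group throughout. Slide 1 holds 1 array of each wild-type group and 2 of each knockout group, and slide 2 holds 2 and 1. Within slide 1, IIAEK in wild type is therefore 1 array against 1, as is IIAEK in the knockout within slide 2. No direction by slide can be read from such a pair. Each genotype has the same slide layout on both treatments. Slide as a block thus cannot change the size of an IIAEK effect or of the interaction, only the spread.

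Akp3, the targeted gene, was detected in wild type only. Its level was -3.81 and -4.43 in wild-type vehicle replicates 1 and 2 and -6.42, below detection, in replicate 3. In wild type on IIAEK it was -4.39, -1.61 and -1.74 in replicates 1, 2 and 3. All 6 knockout arrays lay below detection, between -5.96 and -7.33. In the second Akp3 probe the signal was above background only on wild-type IIAEK replicates 2 and 3, at -2.29 and -2.14. The group means of the first were -4.89 ± 1.36 (SD) and -2.58 ± 1.57 in wild type and -6.57 ± 0.69 and -6.98 ± 0.50 in the knockout, on vehicle and IIAEK respectively. Over both treatments the knockout was at least 3.14-fold lower (log2 change -3.04, SE 0.55), a difference that missed the threshold over all genes (limma adjusted p = 0.222). This difference in Akp3 level was -2.66 within slide 1, -3.26 within slide 2 and -2.96 with slide as a block, each against knockout signals below detection. Without wild-type IIAEK replicate 1 it was -3.50 and passed at an adjusted p of 0.0343, and over the alternatives the adjusted p ranged from 0.0343 to 0.646. Its highest value, 0.646, came with normexp correction on median signals, which brought the change to -0.86.

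The other alkaline phosphatase genes were expressed in all groups. Alpi lay between 4.68 and 5.81 on the wild-type arrays and between 3.99 and 5.06 on the knockout arrays, far above Akp3. Transcript of an intestinal alkaline phosphatase thus remained in the knockout. As a list, the 4 alkaline phosphatases were lower in the knockout over both treatments, with a median log2 change of -0.94, 3 members below 0 and 1 above (camera adjusted p = 0.000147). The call was lost with the adjusted p = 0.844 with an estimated correlation. No member passed over all genes, and 3 passed adjusted over the list alone. The list holds Akp3, the targeted gene, so part of its fall was fixed by the design, and it was not tested without Akp3. Alppl2, an embryonic-type alkaline phosphatase that lies beside Akp3, differed by -1.15 (adjusted p = 0.245), Alpi, a further intestinal alkaline phosphatase, by -0.73 (adjusted p = 0.514) and Alpl, the tissue-nonspecific form, by 0.23 (0.077 without wild-type IIAEK replicate 1 and 0.44 without wild-type IIAEK replicate 3). The list differed by -0.71 within slide 1, -1.15 within slide 2 and -0.93 with slide as a block. Without wild-type IIAEK replicate 1, Alppl2 differed by -1.34 and passed at an adjusted p of 0.0343, within a range of 0.0262 to 0.789 over the alternatives.

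**Figure D1:**
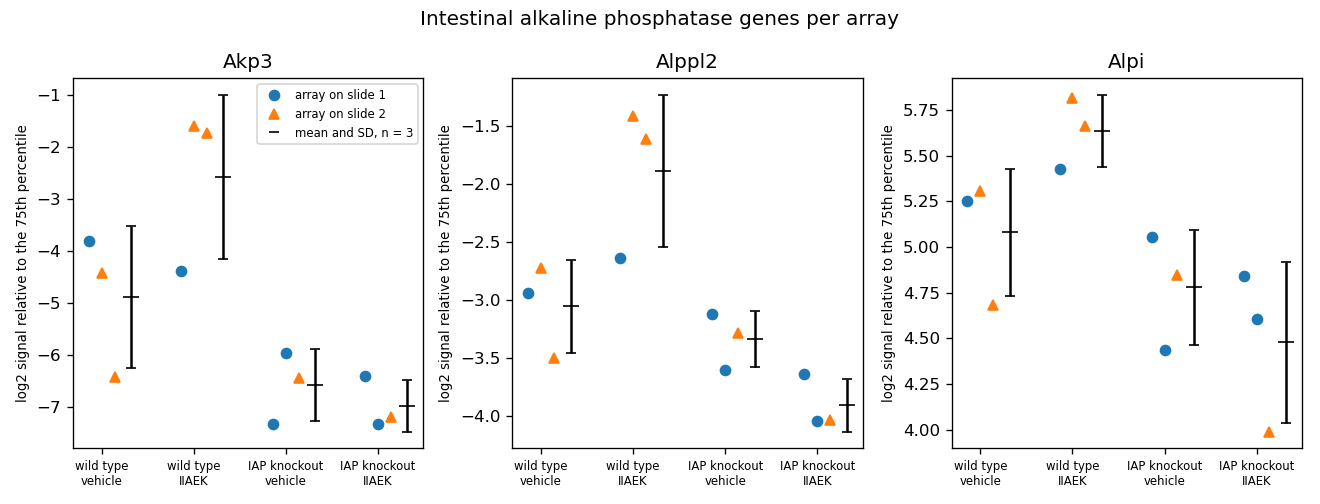
Levels of Akp3, Alppl2 and Alpi on each array (log2 relative to the 75th percentile of the array), with blue circles for slide 1, orange triangles for slide 2 and black marks for the mean and SD of each group (n = 3). Akp3 lies between -5.96 and -7.33 on the knockout arrays, all below detection, and reaches -1.61 on a wild-type IIAEK array.

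In wild-type mice, IIAEK was compared with vehicle to see what the peptide changes when Akp3 is intact. All 4 alkaline phosphatases were above 0, with a median log2 change of 0.86 (camera adjusted p = 0.0022; adjusted p = 0.629 with an estimated correlation). Akp3 changed by 2.31 (SE 0.78), Alppl2 by 1.17 (SE 0.30), Alpi by 0.55 (SE 0.25) and Alpl by 0.56. Each missed the threshold over all genes, and 2 passed adjusted over the list alone. The list changed by 0.21 within slide 1 and 1.17 within slide 2. For Akp3, IIAEK in wild type gave -0.58 within slide 1, from 1 array against 1, and 3.75 within slide 2, from 2 against 2, and for Alppl2 the values were 0.31 and 1.60. Without wild-type vehicle replicate 3, the change of Alpi was 0.35. That of Alpl was 0.15 without wild-type IIAEK replicate 3 and 0.87 without wild-type IIAEK replicate 1.

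Smooth muscle genes were higher as a list in wild type on IIAEK, 12 of 13 above 0, with a median of 0.89 (camera adjusted p = 8.33e-08). This call was lost with the adjusted p = 0.629 with an estimated correlation. Des, the muscle intermediate filament protein desmin, changed by 1.17 (SE 0.30), Acta2, smooth muscle actin, by 1.14, Synm, synemin, by 0.90 and Smtn, smoothelin, by 0.89. None passed over all genes and 7 passed adjusted over the list alone. Genes of fibroblasts and matrix were also higher, with a median of 0.47 and 11 of 14 above 0 (adjusted p = 0.00138; adjusted p = 0.629 with an estimated correlation), led by the collagen gene Col1a1 at 1.58 (SE 0.49) and Sparc at 1.23. Genes of proliferation had a median of 0.41 with 19 of 26 above 0 (adjusted p = 0.000221; adjusted p = 0.703 with an estimated correlation), among them the replication genes Mcm5 at 0.87, Mcm3 at 0.79 and Mcm7 at 0.64. Within slide 1 the medians of these 3 lists were 0.030, 0.0037 and -0.0025, and within slide 2 they were 1.30, 0.65 and 0.61. With slide as a block they were 0.89, 0.47 and 0.41. Without wild-type IIAEK replicate 3 the median was 0.48 for smooth muscle and 0.17 for proliferation. Lists of other cells beneath the epithelium were called higher in the same comparison, adipose and mesentery with a median of 0.73 (camera adjusted p = 0.0371; adjusted p = 0.698 with an estimated correlation), enteric neurons and glia with 0.29 (adjusted p = 0.0258) and endothelium with 0.27 (adjusted p = 0.0366; both 0.629 with an estimated correlation). The adipose call ended without wild-type vehicle replicate 2 (0.57) or wild-type IIAEK replicate 2 (0.57). Those of enteric neurons and endothelium ended without wild-type vehicle replicate 1 (0.35 and 0.17) or wild-type IIAEK replicate 3 (both 0.19).

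Genes of brush border digestion were lower in the same comparison, 14 of 16 below 0, with a median of -0.44 (camera adjusted p = 0.00165; adjusted p = 0.629 with an estimated correlation). Enpep, glutamyl aminopeptidase, changed by -1.24 (SE 0.33), Dpp4, dipeptidyl peptidase 4, by -1.12 and Sis, sucrase-isomaltase, by -0.41. Over the list alone 3 passed, and 0 passed over all genes. The median was 0.070 within slide 1 and -0.85 within slide 2, and -0.68 without wild-type vehicle replicate 1. Lists of the distal small intestine, xenobiotic metabolism and triglyceride synthesis were called too. The mean log2 deviations of their genes from the mean over all arrays were 0.28, 0.25 and 0.11 in wild type on vehicle. On IIAEK they were -0.29, -0.080 and -0.097. With an estimated correlation these calls ended. Genes of fatty acid synthesis were higher, 14 of 15 above 0, with a median of 0.36 (adjusted p = 0.00419; adjusted p = 0.629 with an estimated correlation). Fasn, fatty acid synthase, changed by 1.11, Fads2 by 0.76, Acaca by 0.66 and Acly by 0.48. That median was 0.034 within slide 1 and 0.53 within slide 2, and it was 0.22 without wild-type vehicle replicate 3 and 0.55 without wild-type vehicle replicate 1.

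Genes of cholesterol synthesis and SREBP2 targets were higher in wild type on IIAEK, 16 of 25 above 0, with a median of 0.25 (camera adjusted p = 0.0459; adjusted p = 0.703 with an estimated correlation). The pathway enzymes Fdps, Pmvk and Msmo1 changed by 0.78, 0.48 and -1.05. No member passed over all genes or adjusted over the list alone, and 9 had an unadjusted p under 0.05 in limma. The call ended without wild-type vehicle replicate 3 (0.14), wild-type IIAEK replicate 1 (0.22), wild-type IIAEK replicate 3 (0.16) or knockout vehicle replicate 1 (0.25, as that array enters only the spread). Within slide 1 the median was 0.048 and within slide 2 it was 0.41.

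Among genes of sterol and peptide handling, Abca1, the cholesterol exporter of the basolateral membrane, changed by -0.71 (SE 0.20, adjusted p = 0.369) in wild type on IIAEK, with -0.39 within slide 1 and -0.87 within slide 2, and its other probe gave -0.76. Slc15a1, the peptide transporter PEPT1, changed by -0.84 (SE 0.61), between -0.48 without wild-type vehicle replicate 2 and -1.47 without wild-type vehicle replicate 1. Abcg8, which forms the sterol efflux pump with Abcg5, changed by 0.31 (0.12 to 0.58 without 1 array at a time) and Apob, the protein of chylomicrons, by -0.23 (-0.058 in its other probe). Soat2, Abcg5, Npc1l1 and Mttp lay between -0.09 and 0.09. None of these 8 genes passed the threshold.

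**Figure D2:**
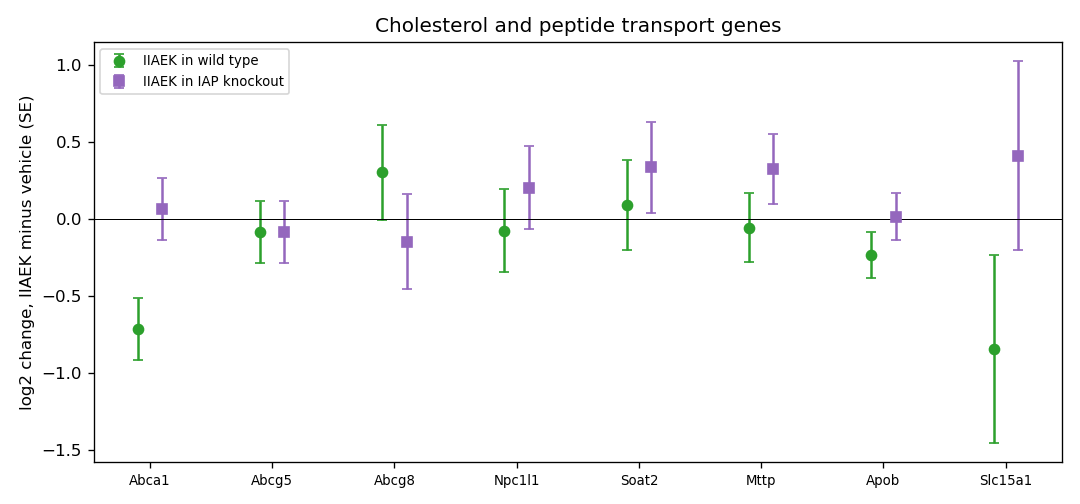
Log2 change of 8 genes of sterol and peptide handling, IIAEK minus vehicle, with the limma SE, green circles for wild type and purple squares for the knockout (n = 3 arrays per group). Abca1 lies at -0.71 in wild type and 0.07 in the knockout, and no gene passed the threshold in either genotype.

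In limma, 0 genes passed in wild type on IIAEK, against 3591 (13.0%) at an unadjusted p under 0.05, and 1 passed without wild-type IIAEK replicate 1 and 1 with slide as a block. The smallest adjusted p was 0.369, shared by the 10 characterised genes of smallest p, which are given as not passing. They were Dusp9, a MAP kinase phosphatase, at -2.36 (SE 0.40, at least 3.14-fold lower), Acta1, skeletal muscle actin, at 1.54 (SE 0.29), Aspa at -1.53, Slc38a11 at -1.04, Ccdc24 at 1.03, C1qtnf5 at 0.97, Coq8a at 0.97, Prr15 at -0.92, Radx at -0.91 and Slc51b, a subunit of the basolateral bile acid exporter, at -0.85. Of 42 lists 15 were called. Exocrine pancreas genes were among them, with a median of 2.49 (adjusted p = 0.0134; adjusted p = 0.731 with an estimated correlation), -3.23 within slide 1 and 5.50 within slide 2, and -0.52 without wild-type IIAEK replicate 3. B and plasma cell genes had a median of 1.11 (adjusted p = 0.0258; adjusted p = 0.703 with an estimated correlation), a call that ended without wild-type vehicle replicate 1 (0.62) or 2 (0.76) or wild-type IIAEK replicate 2 (0.43), and the median was 1.94 without wild-type vehicle replicate 3 and 1.84 without wild-type IIAEK replicate 1. All 15 were called within slide 2 and kept their call with slide as a block. The block is a weak check here, since both wild-type groups have the same slide layout and the medians cannot move with it. Slide 1, with 1 wild-type array per treatment, is no check of the 15 calls. Without the 2 arrays highest in pancreas genes 8 lists kept their call.

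**Figure D3:**
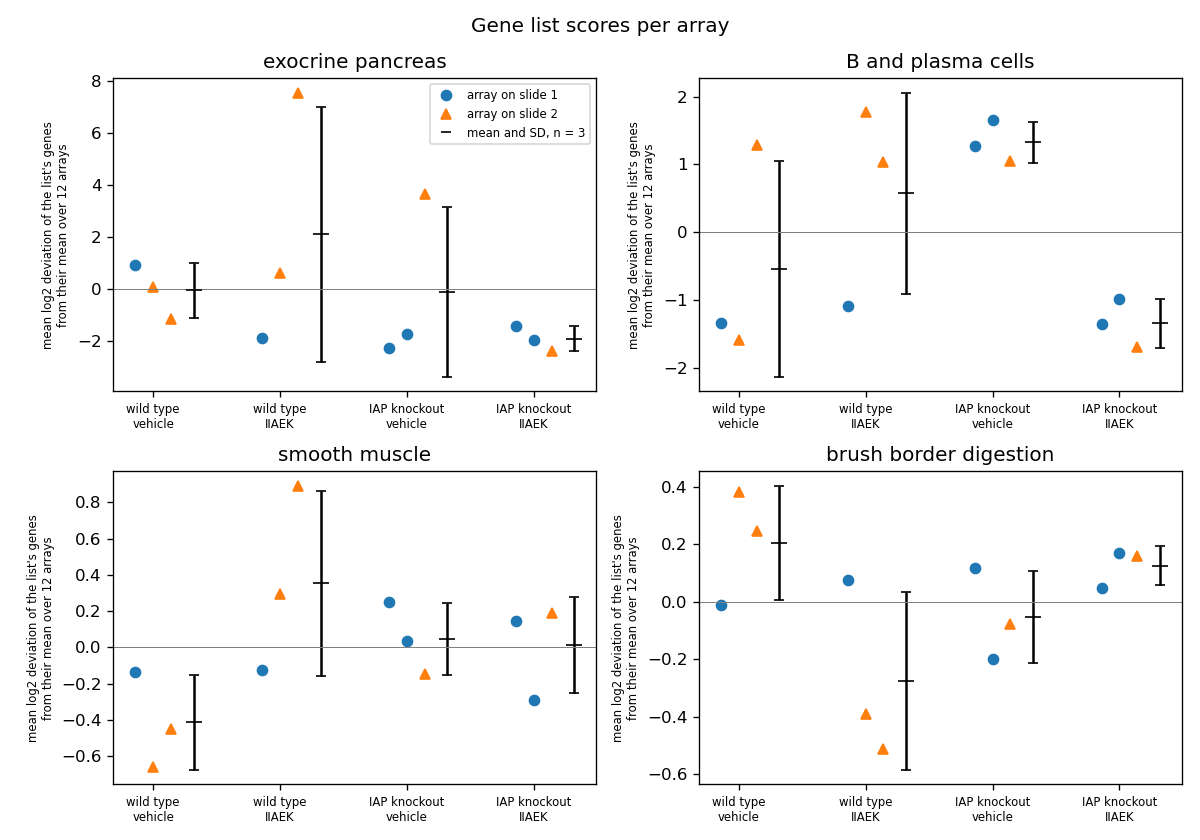
Mean log2 deviation of the genes of 4 lists (exocrine pancreas, B and plasma cells, smooth muscle, brush border digestion) from their mean over the 12 arrays, for each array, with blue circles for slide 1, orange triangles for slide 2 and black marks for the mean and SD of each group (n = 3). Pancreas genes stand at 7.55 on wild-type IIAEK replicate 3 and 3.66 on knockout vehicle replicate 3, and B cell genes lie between -1.70 and -0.98 on the knockout IIAEK arrays.

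In knockout mice, IIAEK was compared with vehicle to see what the peptide changes without Akp3, while Alpi was still expressed. B and plasma cell genes were lower, 11 of 13 below 0, with a median log2 change of -2.65 (camera adjusted p = 3.16e-10; adjusted p = 0.464 with an estimated correlation). Tnfrsf13c, the BAFF receptor, changed by -2.65 (SE 0.71). Cxcr5, the homing receptor for follicles, was at least 11.5-fold lower and Fcer2a, a low-affinity IgE receptor, at least 7.46-fold lower. No member passed over all genes and 9 passed adjusted over the list alone. The median was -2.47 within slide 1, -3.01 within slide 2 and -2.65 with slide as a block, and the call held when any 1 of the 12 arrays was left out. The mean score of the list was 1.32 ± 0.30 (SD) on vehicle and -1.35 ± 0.36 on IIAEK, while wild-type vehicle arrays spanned -1.59 to 1.29.

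Genes of MHC class II presentation were lower with them, 9 of 10 below 0 and a median of -0.60 (adjusted p = 0.000591; adjusted p = 0.806 with an estimated correlation). The members with the smallest p, H2-Ob at -2.06 and H2-Oa at -1.43, are chiefly expressed by B cells, followed by Ciita at -0.86 and Cd74 at -0.78. Tuft cell genes had a median of -0.20 with 10 of 12 below 0 (adjusted p = 0.00721; adjusted p = 0.464 with an estimated correlation), led by Spib at -1.53, a transcription factor that B cells express too, with the tuft genes Chat at -0.68 and Avil at -0.60. Immediate early genes had a median of -0.45 with 16 of 18 below 0 (adjusted p = 7.31e-05; adjusted p = 0.629 with an estimated correlation), among them Egr3 at -1.35, Fosb at -1.25, Nr4a1 at -1.06 (SE 0.26) and Klf2 at -0.96. Paneth cell genes were higher, 8 of 11 above 0, with a median of 0.56 (adjusted p = 0.0024; adjusted p = 0.75 with an estimated correlation), among them Mptx2 at 1.37, Defa21 at 1.36, Ang4 at 1.21 and Mmp7 at 0.91. All 4 calls ended without knockout IIAEK replicate 3, where the medians were -0.15, -0.11, -0.26 and 0.34. Without knockout vehicle replicate 3 the medians of immediate early and Paneth genes were -0.20 and 0.33, without knockout vehicle replicate 1 that of tuft genes was -0.31, and without knockout IIAEK replicate 2 that of MHC class II genes was -0.93. Within slides 1 and 2 they were -0.28 and -1.28 (MHC class II), -0.12 and -0.48 (tuft), -0.081 and -0.92 (immediate early) and 0.14 and 1.39 (Paneth).

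Among alkaline phosphatases in the knockout, Alppl2 changed by -0.57, Alpi by -0.30 and Alpl by 0.12, and Akp3 stayed below detection. Leaving out 1 array at a time, Alpi ranged from -0.48 (without knockout IIAEK replicate 1) to -0.055 (without knockout IIAEK replicate 3), and Alpl from -0.046 (without knockout vehicle replicate 1) to 0.33 (without knockout IIAEK replicate 3). The sterol and peptide genes lay between -0.15 for Abcg8 and 0.41 for Slc15a1 (-0.11 to 0.94 without 1 array at a time), with Abca1 at 0.07 (-0.50 in its other probe) and Mttp at 0.33, and none passed. In limma 0 genes passed, against 1217 (4.42%) at an unadjusted p under 0.05. With only the knockout arrays 14 passed. The characterised genes of smallest p, all with an adjusted p of 0.910, were Fcrl1, a B cell receptor-like protein, at -3.10 (SE 0.72; -2.43 and -2.69 in its other probes), Siglecg, a brake on B cells, at -2.21 (SE 0.46), Vpreb3 at -1.47 (SE 0.29), Gpnmb at -1.30, Noxred1 at -0.96, Slc25a29 at -0.91, Prr36 at -0.87, Pip4k2b at -0.73, Gdnf at -0.71 and Efcab11 at 0.73. Of 42 lists 11 were called, and 1, the B cell list, kept its call without every array in turn. Exocrine pancreas genes moved here too, with a median of -2.13 (adjusted p = 0.0415; adjusted p = 0.806 with an estimated correlation), 0.24 within slide 1 and -7.13 within slide 2. Their call ended without knockout vehicle replicate 3 (0.11), knockout IIAEK replicate 1 (-2.60) or knockout IIAEK replicate 3 (-1.88), and the median was -3.40 without knockout vehicle replicate 1.

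The interaction asks whether the change on IIAEK differed between the genotypes; negative values mean a lower change in the knockout. B and plasma cell genes had a median of -3.76, with 10 of 13 below 0 (camera adjusted p = 4.94e-06; adjusted p = 0.633 with an estimated correlation), and 10 passed adjusted over the list alone. Smooth muscle genes had a median of -0.88 with 12 of 13 below 0 (adjusted p = 0.000145; adjusted p = 0.633 with an estimated correlation). Brush border genes had a median of 0.54 with 13 of 16 above 0 (adjusted p = 0.0057; adjusted p = 0.633 with an estimated correlation), among them the peptidases Enpep at 1.82, Dpp4 at 1.73, Mep1a at 1.32 and Mep1b at 1.22, and 5 passed adjusted over the list alone. All 4 alkaline phosphatases lay below 0, with a median of -1.29 (adjusted p = 0.00801; adjusted p = 0.633 with an estimated correlation), Alppl2 at -1.74 (SE 0.43), Alpi at -0.85 and Alpl at -0.44 (-0.030 without wild-type IIAEK replicate 3). The fourth, Akp3 at -2.71, lay below detection on all 6 knockout arrays. Its change in the knockout was thus not measured, and this value is no measured difference. The median and the call of the alkaline phosphatase list include Akp3, and the list was not tested without it. In the order given, the medians of the 4 lists were -3.08, -0.21, 0.21 and 0.013 within slide 1 and -4.36, -0.91, 1.09 and -1.97 within slide 2. Without wild-type IIAEK replicate 3 the smooth muscle median was -0.59, and without wild-type vehicle replicate 1 the brush border median was 0.86.

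Of single genes, 0 passed the interaction in limma, against 4157 (15.1%) at an unadjusted p under 0.05, and 455 passed with array weights. Abca1 was at 0.78 (SE 0.28, adjusted p = 0.311) but at 0.26 in its other probe. Slc15a1 was at 1.26, Abcg8 at -0.45 and Mttp at 0.38, with ranges of 0.73 to 1.89, -0.72 to -0.17 and 0.21 to 0.61 without 1 array at a time, and none of the sterol and peptide genes passed. The smallest adjusted p, 0.197, belongs to a probe without a symbol. The 10 characterised genes of smallest p, all with an adjusted p of 0.311, were Vpreb3 at -2.22, Fermt3 at -1.81, Top1mt at -1.53, Mtss2 at -1.47, Rpusd1 at -1.28, Polh at -1.17, Dennd10 at 1.42, Grm5 at 1.40, Radx at 1.35 and Prr15 at 1.35. Of 42 lists 15 were called, 6 of which kept their call without each array, and 3 were called within slide 1 and 11 within slide 2, where 2 of the 4 groups hold 1 array.

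On vehicle, the knockout was compared with wild type in the absence of the peptide. This comparison does not isolate the loss of Akp3, since the knockout has more of its arrays on slide 1. A targeted locus can also carry DNA of another strain. B and plasma cell genes were higher in the knockout, 10 of 13 above 0, with a median of 1.86 (camera adjusted p = 0.000521; adjusted p = 0.823 with an estimated correlation). Tnfrsf13c differed by 1.86, and Cd79b and Cd79a, the signalling chains of the B cell receptor, by 1.34 and 1.11. No member passed over all genes or adjusted over the list alone. The 3 wild-type vehicle arrays differ among themselves by 2.88 in the mean score of this list. Smooth muscle genes had a median of 0.43 with 12 of 13 above 0 (adjusted p = 0.000521; adjusted p = 0.823 with an estimated correlation), among them Acta2 at 0.90 and Myh11, smooth muscle myosin, at 0.90. Adipose genes had a median of 0.66 with 10 of 10 above 0 (adjusted p = 0.0015; adjusted p = 0.823 with an estimated correlation), Pnpla2, adipose triglyceride lipase, at 0.76 and Cidea at 0.51. Tuft cell genes had a median of 0.35 with 11 of 12 above 0 (adjusted p = 0.0011; adjusted p = 0.714 with an estimated correlation), led by Spib at 1.24, which B cells express too, with Avil at 0.77 and Alox5 at 0.44. The medians of these lists were 2.91, 0.31, 0.80 and 0.23 within slide 1, 1.23, 0.22, 0.84 and 0.63 within slide 2, and 2.09, 0.43, 0.66 and 0.36 with slide as a block. All 4 kept their call without each array in turn, and without knockout vehicle replicate 3 the adipose median was 1.05.

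Among heat shock genes on vehicle 10 of 14 lay below 0, with a median of -0.29 (adjusted p = 0.0391; adjusted p = 0.823 with an estimated correlation) and 3 past the threshold adjusted over the list alone. The chaperone genes Dnaja1, Chordc1 and Hsp90aa1 differed by -0.72, -0.69 and -0.57. That call ended without wild-type vehicle replicate 2 (-0.13), knockout vehicle replicate 3 (-0.15), wild-type IIAEK replicates 1 or 3, or knockout IIAEK replicate 1; the last 3 do not enter the median. The median was -0.057 within slide 1 and -0.61 within slide 2. Akp3 differed by -1.69 (at least 1.28-fold lower, adjusted p = 0.441), Alppl2 by -0.28, Alpi by -0.30 and Alpl by 0.45. Without wild-type vehicle replicate 3, Alppl2 and Alpi both differed by -0.50; Alppl2 differed by -0.12 without wild-type vehicle replicate 2, Alpi by -0.13 without knockout vehicle replicate 2 and Alpl by 0.29 without wild-type vehicle replicate 1. In limma 0 genes passed, against 3132 (11.4%) at an unadjusted p under 0.05, and 2 passed without wild-type vehicle replicate 3 or without knockout vehicle replicate 1. With array weights the count was 1540, and with only the vehicle arrays it was 1. The characterised genes of smallest p, with an adjusted p of 0.348, were Utp14b, a gene of ribosome assembly, at -2.51 (SE 0.39), Glrp1 at -2.11 (at least 1.28-fold lower), Pm20d1, an enzyme that makes N-acyl amino acids, at 1.27, Wdr44 at -0.79 and Ddx59 at 0.75. They were followed at 0.423 by Ctse at 1.66, Top1mt at 1.08, Zfp395 at 1.07, Radx at -1.004 and Kpna4 at -0.72. Of the genes named here, Utp14b, Glrp1, Pm20d1 and Ddx59 lie within 60 Mb of Akp3 on chromosome 1, a window chosen after the values were seen. Of 42 lists 11 were called, and 4 kept their call without each array.

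On IIAEK, the knockout was compared with wild type to see how the genotypes differ under the peptide. The 4 alkaline phosphatases had a median of -1.59 with 3 below 0 (camera adjusted p = 9.38e-06; adjusted p = 0.572 with an estimated correlation), and 3 passed adjusted over the list alone. The list holds the targeted gene Akp3, so part of this fall was fixed by the design, and the list was not tested without it. Akp3 was at least 7.71-fold lower (-4.40, adjusted p = 0.390). Alppl2 differed by -2.02 (SE 0.30, adjusted p = 0.235), Alpi by -1.15 (adjusted p = 0.611) and Alpl by 0.01 (-0.30 to 0.42 without 1 array at a time). Without wild-type IIAEK replicate 1, Alppl2 differed by -2.39 and passed. The list differed by -0.95 within slide 1, -2.13 within slide 2 and -1.58 with slide as a block. Brush border genes had a median of 0.45 with 14 of 16 above 0 (adjusted p = 0.000585; adjusted p = 0.829 with an estimated correlation), Enpep at 1.06, Xpnpep2 at 0.85, Dpp4 at 0.75 and Mgam, maltase-glucoamylase, at 0.43. That median was 0.047 within slide 1 and 0.70 within slide 2.

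B and plasma cell genes were lower in the knockout on IIAEK, 10 of 13 below 0, with a median of -1.89 (adjusted p = 1.47e-05; adjusted p = 0.829 with an estimated correlation), -0.099 within slide 1, -3.13 within slide 2 and -1.67 with slide as a block. Fcer2a was at least 4.92-fold lower and Tnfrsf13c differed by -1.89. Exocrine pancreas genes had a median of -4.82 with 15 of 16 below 0 (adjusted p = 2.13e-06; adjusted p = 0.829 with an estimated correlation), 0.13 within slide 1, -7.58 within slide 2 and -1.64 without wild-type IIAEK replicate 3. Pnlip, pancreatic lipase, differed by -6.12 (SE 2.75), and Zg16 and Clps of this list are also made by gut epithelium. Interferon-stimulated genes had a median of -0.42 with 23 of 24 below 0 (adjusted p = 0.0123; adjusted p = 0.883 with an estimated correlation), Ifi44 at -0.98, Oas2 at -0.90 and Irf7 at -0.40, but 0.47 within slide 1 and -1.25 within slide 2. This last call ended without wild-type IIAEK replicate 2 (-0.18) or knockout IIAEK replicate 3 (0.037).

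Of single genes, 0 passed on IIAEK in limma, against 2111 (7.66%) at an unadjusted p under 0.05, and 2 passed without wild-type vehicle replicate 3, wild-type IIAEK replicate 1 or knockout vehicle replicate 1. With slide as a block 1 passed, and with only the IIAEK arrays 4. Smallest in p among characterised genes were Glrp1 at -2.47 (adjusted p = 0.138, at least 1.34-fold lower), Pam, which amidates peptides, at 2.66 (adjusted p = 0.235; -0.0087 in its other probe), Alppl2, Akp3 and Cfap100 at -3.12 (adjusted p = 0.390, at least 3.25-fold lower). Grk5 at -0.86, Grm5 at 0.98, Rab7b at -1.38, Pm20d1 at 1.03 and Stk25 at -1.79 (-1.97 in its other probe) had adjusted p-values of 0.412 to 0.513. Of 42 lists 11 were called, and 4 kept their call without each array.

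Averaged over both genotypes, IIAEK left 0 genes past the threshold in limma, against 938 (3.40%) at an unadjusted p under 0.05, and 1 passed without wild-type IIAEK replicate 1 or knockout vehicle replicate 3, and 1 with array weights. Genes of cholesterol synthesis and SREBP2 targets were higher as a list, 20 of 25 above 0, with a median of 0.16 (camera adjusted p = 0.000511; adjusted p = 0.615 with an estimated correlation), Mvd at 0.60 and Fdft1, squalene synthase, at 0.43. Genes of proliferation had a median of 0.22 with 25 of 26 above 0 (adjusted p = 1.09e-07; adjusted p = 0.615 with an estimated correlation), and smooth muscle genes a median of 0.44 with 12 of 13 above 0 (adjusted p = 1.3e-07; adjusted p = 0.615 with an estimated correlation). Genes of erythroid blood had a median of -1.11 with 6 of 6 below 0 (adjusted p = 0.000256; adjusted p = 0.615 with an estimated correlation). Of 42 lists 17 were called and 5 kept their call without each array, all 4 of these among them. Proliferation lost it without the 2 arrays highest in pancreas genes (0.050), where the other 3 kept it at 0.086, 0.20 and -0.51. With array weights the calls of cholesterol synthesis (0.025), proliferation (0.064) and erythroid blood (-0.46) ended. Without knockout IIAEK replicate 1 the cholesterol median was 0.078, without wild-type IIAEK replicate 3 those of proliferation and smooth muscle were 0.12 and 0.27, and without knockout vehicle replicate 3 that of erythroid genes was -0.58. In the order given the medians were 0.044, -0.019, -0.091 and -0.065 within slide 1 and 0.26, 0.42, 0.84 and -2.36 within slide 2. Characterised genes among those of smallest p, all with an adjusted p of 0.962, were Fras1 at -1.70, Pdilt at -0.91, Ch25h, cholesterol 25-hydroxylase, at -0.87, Meox2 at 0.80, Rasl11b at 0.71, Ndn at 0.59, Kcns1 at -0.50, Aim2 at -0.49 and Ociad1 at 0.48. Among alkaline phosphatases, Alpl was at 0.34, Alppl2 at 0.30 and Alpi at 0.13. The value of Akp3, 0.95, averages wild type with a knockout that lay below detection on all 6 arrays, and is no measured change. Without wild-type vehicle replicate 3 Alpi was at 0.027, and the lowest values of Alpl and Alppl2 were 0.13 without wild-type IIAEK replicate 3 and 0.18 without wild-type IIAEK replicate 2. Abca1 was at -0.32 (-0.63 in its other probe), Slc15a1 at -0.21 (-0.53 to 0.050 without 1 array at a time), Apob at -0.11 and Abcg5 at -0.08, and Abcg8, Npc1l1, Soat2 and Mttp lay between 0.07 and 0.21.

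Averaged over both treatments, 1 gene differed between the genotypes. Glrp1, a glutamine-rich protein gene on chromosome 1, was lower in the knockout by a log2 change of -2.29 (SE 0.22, limma adjusted p = 0.00885), at least 1.31-fold, and all 6 knockout arrays lay below detection. Its adjusted p ranged from 0.000906 to 0.530 over the alternatives. The call ended within slide 1 (-1.88, adjusted p = 0.367), without knockout IIAEK replicate 2 (-2.30, adjusted p = 0.0517), without the 2 arrays highest in pancreas genes (-2.27, adjusted p = 0.153), and with normexp correction on median signals (-0.28, adjusted p = 0.530). For Glrp1, IAP knockout against wild type over both treatments gave -2.30 with slide as a block and -2.72 within slide 2, where it passed at an adjusted p of 0.0328. Next in p among characterised genes, without passing, were Pam at 2.25 (SE 0.29, adjusted p = 0.0630; 0.13 in its other probe), Pm20d1 at 1.15 (SE 0.15, adjusted p = 0.0630), Ddx59 at 0.66 (adjusted p = 0.0779), Cfap100 at -2.74 and Utp14b at -1.84 (both 0.0782), Stk25 at -1.49 (-1.60 in its other probe), Rab7b at -1.09, Akp3 and Eml5 at 0.59. The count of 1 compares with 1479 genes (5.37%) at an unadjusted p under 0.05. It was 4 without wild-type vehicle replicate 3, 8 without wild-type IIAEK replicate 1, 10 without knockout vehicle replicate 1 and 0 without knockout IIAEK replicate 2, and 79 with array weights.

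Beside the alkaline phosphatases, 9 lists were called between the genotypes over both treatments. Interferon-stimulated genes had a median of -0.33 with 23 of 24 below 0 (camera adjusted p = 0.000354; adjusted p = 0.956 with an estimated correlation), 0.32 within slide 1 and -1.60 within slide 2, a call that ended without knockout vehicle replicate 3 (-0.096) or knockout IIAEK replicate 3 (-0.18). Heat shock genes had a median of -0.22 with 11 of 14 below 0 (adjusted p = 0.00165; adjusted p = 0.956 with an estimated correlation), Chordc1 at -0.37, Dnaja1 at -0.34 and Hsp90aa1 at -0.32, which ended without wild-type IIAEK replicate 3 (-0.19) or knockout IIAEK replicate 3 (-0.18). Exocrine pancreas genes had a median of -2.40 with 16 of 16 below 0 (adjusted p = 0.000281; adjusted p = 0.956 with an estimated correlation), a call that ended without wild-type IIAEK replicate 3 (-0.81) and with slide as a block (-1.45). Of the knockout arrays 4 of 6 lie on slide 1, and of the wild-type arrays 2 of 6. The other 6 called lists had medians between -0.35 (MHC class II) and 0.44 (adipose), and each call ended without at least 4 of the 12 arrays in turn and with an estimated correlation (adjusted p = 0.956). Those of MHC class II, tuft cells (0.15) and adipose also ended with slide as a block.

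Genes close to Akp3 were compared with the rest of the genome. Fisher's exact test treats the genes as independent, though all come from the same mice, so its p-values do not measure variation between mice. Of 203 tested genes within 20 Mb of Akp3 on chromosome 1, 1 (Glrp1) differed between the genotypes over both treatments, against 0 of 15586 elsewhere (Fisher's exact test, two-sided, p = 0.0129). Within 10 Mb it was 1 of 127 (Fisher's exact p = 0.00804). With 1 gene called in all, these p-values are only the share of the placed genes that lie in the window. They add nothing to the call of Glrp1. On vehicle alone and on IIAEK alone no gene passed in the window or outside it. The list of genes near Akp3 fixed with the others held, Akp3 left out, 52 tested genes: 0 passed, 1 had an unadjusted p under 0.001 in limma, against 21 of 15736 elsewhere (Fisher's exact p = 0.0701), and 6 had one under 0.01, against 172 (Fisher's exact p = 2.50e-05). The count in the window was 2 without wild-type vehicle replicate 3, 3 without wild-type IIAEK replicate 1, 3 without knockout vehicle replicate 1 and 0 without knockout IIAEK replicate 2. At an unadjusted p under 0.001 in limma, a threshold chosen after the values were seen, 12 of 909 tested genes of chromosome 1 (1.32%) differed, against at most 1 gene on every other chromosome.

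**Figure D4:**
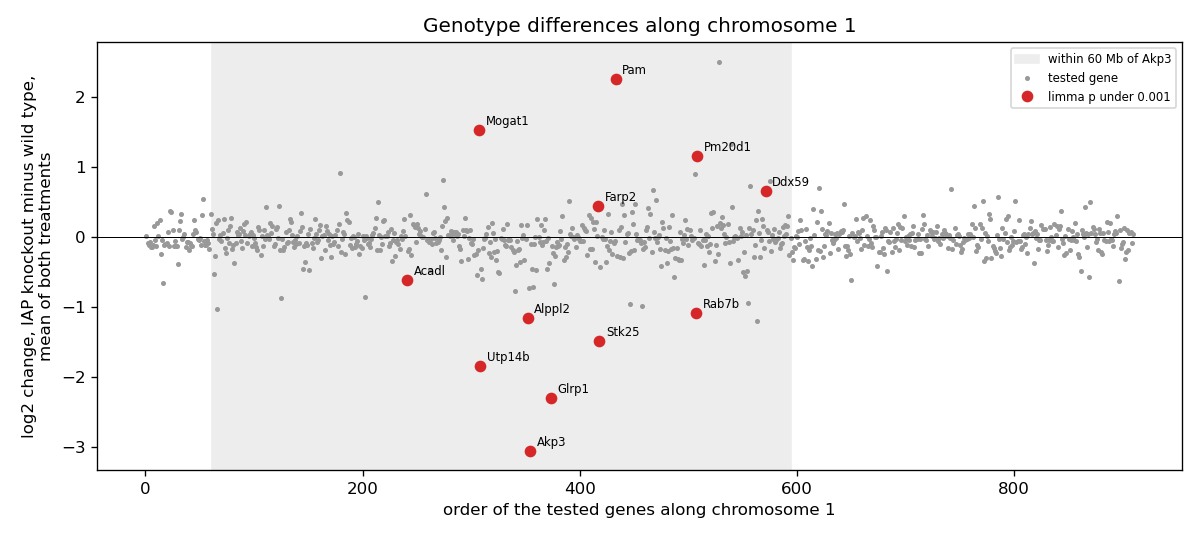
Log2 change, knockout minus wild type over both treatments, of the tested genes of chromosome 1 in their order on assembly GRCm38.p6, with genes within 60 Mb of Akp3 shaded (a window chosen after the values were seen), those with a limma p under 0.001 in red and the others in grey. The 12 labelled genes, Akp3 at -3.04 and Glrp1 at -2.29 among them, all lie in the shaded part.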

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

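The tests of pancreatic tissue and of a response to IIAEK in the pancreas pattern, and of slide and of an IIAEK effect in the B cell pattern, were chosen after the result was seen, as were the use of the 14 members against faulty spots, the count over all 200 splits and the fit without the 2 arrays highest in pancreas genes.

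For 15 lists the change on IIAEK differed between the genotypes in camera at its preset correlation, and these differences single them out. Lower in the knockout than in wild type were the changes of exocrine pancreas genes (median log2 difference -4.70), B and plasma cells (-3.76), alkaline phosphatases (-1.29), adipose and mesentery (-0.90), smooth muscle (-0.88), MHC class II presentation (-0.76), endothelium (-0.63), fatty acid synthesis (-0.46), fibroblasts and matrix (-0.39) and tuft cells (-0.34). The value of alkaline phosphatases includes Akp3, which lay below detection on every knockout array, and the list was not tested without it. The call of pancreas genes ended without wild-type IIAEK replicate 3 (-1.53) or knockout vehicle replicate 3 (-2.54), and their median was 0.49 without both. Higher were those of the distal small intestine (0.91), antimicrobial peptides (0.79), brush border digestion (0.54), Paneth cells (0.52) and triglyceride synthesis (0.21). Of the 15 lists, only 6 kept their call without each array in turn, and 14 kept it with slide as a block. That block cannot change their medians, since each genotype has the same slide layout on both treatments. With an estimated correlation no list passed: the adjusted p was 0.633 for B cells, alkaline phosphatases, adipose, smooth muscle, endothelium, tuft cells, distal small intestine, antimicrobial peptides and brush border, and 0.729 for the other 6. Of 100 splits of the arrays, 25 gave at least 15 lists, with 22 in the highest of the others, so chance cannot be excluded for their number. For genes the real count was 0, which all 100 splits reach whatever they hold (highest other 0), so the splits test nothing there. Over all 200 possible splits, 51 gave at least 15 lists (highest other 23), and the highest other count of genes was 145, a sign of structure in the samples whose source was not tested. Members that led their lists were the bile acid exporter subunit Slc51b at 0.87, the hormone gene Nts at 2.34 and the lectin gene Reg3b at 1.63, none of which passed over all genes.

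Exocrine pancreas genes stood far above the other arrays on wild-type IIAEK replicate 3 and knockout vehicle replicate 3, with mean scores of 7.55 and 3.66 against -2.38 to 0.91 elsewhere. The trypsinogen gene Prss2 was at 6.87 and 2.02 on these arrays against a median of -5.35 on the others, and 14 of the 16 tested members had these as their 2 highest arrays, as pancreatic tissue in the collected piece would give; Zg16 and Clps are also made by gut epithelium. A response to IIAEK in wild type is argued against by the lowest wild-type IIAEK array, which lay below the highest wild-type vehicle array (difference -2.81). Faulty spots are argued against by these 14 members, each with a probe on its own spot; the 1 other detected probe of a member was highest on wild-type IIAEK replicate 3 too. Pancreatic tissue may account for the signal, but no test here separates it from other sources of these transcripts. Without these arrays, pancreas genes turned direction in both genotypes (-0.52 in wild type and 0.11 in the knockout on IIAEK). The 2 arrays were picked as the highest in these genes, so that turn is no separate support.

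B cell genes were lower on all 3 knockout IIAEK arrays (scores -1.70 to -0.98) than on all 3 knockout vehicle arrays (1.06 to 1.65), a difference of -2.67. An even shift between slides cancels in this difference, as each knockout group had 2 arrays on slide 1 and 1 on slide 2. Slide as the cause is thus argued against by the layout. For the same reason the median with slide as a block (-2.65) could not have moved and is no separate check. Within slide 1 the median was -2.47, from 2 arrays against 2, and slide 2 adds a single pair of arrays (-3.01). An uneven share of lymphoid follicles between the pieces stays open and cannot be told apart from a change in B cells. A list of 7 follicle genes had a median change of -0.21, between the marks set for and against this cause and close to the one against. Below 0 lay 4, the follicle chemokines Cxcl13 at -1.03 and Ccl20 at -0.84, the vessel gene Madcam1 at -0.75 and Tnfaip2 at -0.21. Above 0 lay Ccl9 at 0.66, Bst1 at 0.40 and Tnfrsf11b at 0.28. Only Ccl9 had an unadjusted p under 0.05 in limma (0.0392). The same B cell score differed by 2.88 among the 3 wild-type vehicle mice, which received the same treatment. An effect of IIAEK in the knockout stays open as well, since the exact permutation p of 0.1, two-sided, is the smallest that 3 against 3 arrays can give.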

How the results depend on the processing

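The normexp fit on median signals, the fit without the 2 arrays highest in pancreas genes and the alternatives for the chromosome 1 count were added after the data had been seen. A planned normexp correction on mean signals was not run, because the deposited files hold no mean signal. List values are median log2 changes, and a list counts as turned where the direction of camera turned, which for some lists left the median on its former side of 0. Where no reason is given, the cause was not tested.

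The authors' values and the intensity trend with a robust prior kept the call and direction of all 90 called lists, and median scaling of 85, a filter on all arrays of 82, the mean of a gene's probes of 84, quantile normalization of 74, normexp of 75, no filter of 71, slide as a block of 75 and slide 2 alone of 71. Slide 1 alone kept 19 lists, with 45 calls ended and 26 turned, array weights kept 46, and the fit without the 2 pancreas-high arrays kept 54. With an estimated correlation all 90 calls ended. Leaving out 1 array at a time, 871 of 1080 list results were kept, 204 ended and 5 turned. Of 126 values of named genes, 111 kept direction and call within slide 1 and 116 within slide 2. With array weights 89 did (32 more passed), and with slide as a block 125. Slide as a block can change the size only of the differences between genotypes. Signal over background limits the dim genes: the lowest level well above background lay between -6.03 and -4.91, and Akp3 and Glrp1 lay below it in the knockout, so their changes shrank to -0.86 and -0.28 under normexp, which adds an offset of 50 to every signal.

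The replicate number as a block is of use only if the numbers pair the samples, and the values give no clear sign of that. Same-numbered arrays of different groups correlated across genes at -0.25 to 0.35 after removal of the group means (median 0.066), 8 of 18 pairs above 0.1. Other pairs correlated at -0.40 to 0.38 (median -0.0048), 10 of 36 above 0.1. All arrays of replicate 1 lie on slide 1 and all of replicate 3 on slide 2, so a likeness by number cannot be told apart from slide. With that block the number of genes changed was the same in all 7 comparisons, and 87 of the 90 lists kept their call.

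Counts of genes changed, which are 0 in 6 comparisons and 1 for knockout against wild type over both treatments, moved under these settings. Slide as a block gave 1 for IIAEK in wild type and 1 for knockout against wild type on IIAEK. Slide 1 alone gave 1 for IIAEK in wild type, 7 for IIAEK in the knockout, 14 for knockout against wild type on vehicle and 0 for knockout against wild type over both treatments. Slide 2 alone gave 10 for IIAEK in wild type, 19 for IIAEK in the knockout, 11 for knockout against wild type on vehicle, 40 for knockout against wild type on IIAEK, 4 for the interaction, 15 for IIAEK over both genotypes and 114 for knockout against wild type over both treatments. On slide 1 each wild-type group and on slide 2 each knockout group holds 1 array. IIAEK in the knockout on slide 1 and IIAEK in wild type on slide 2 are 2 arrays against 2, and the other counts within a slide involve groups of 1 array, which are assumed to vary like the other groups. With only the arrays compared the counts were 14 for IIAEK in the knockout, 1 for knockout against wild type on vehicle and 4 for knockout against wild type on IIAEK. Array weights gave 1540 for knockout against wild type on vehicle, 455 for the interaction, 1 for IIAEK over both genotypes and 79 for knockout against wild type over both treatments. At an unadjusted p under 0.05 with at least 1.5-fold, without adjustment, the counts were 1565 for IIAEK in wild type, 666 for IIAEK in the knockout, 1175 for knockout against wild type on vehicle, 1021 for knockout against wild type on IIAEK, 3363 for the interaction, 196 for IIAEK over both genotypes and 305 for knockout against wild type over both treatments. For knockout against wild type over both treatments the count was 13 at an adjusted p under 0.1, 4 with quantile normalization, 3 with the trend and robust prior, 2 with normexp, 2 with the mean of a gene's probes, and 0 with the filter on all arrays, where Glrp1 is not tested, and without the pancreas-high arrays.

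Genes near Akp3 that passed numbered 10 with array weights, 2 with quantile normalization, 2 with the mean of a gene's probes, 2 with the trend and robust prior, and 0 with the filter on all arrays, within slide 1 and without the pancreas-high arrays. The Akp3 difference over both treatments was -3.17 with array weights, where it passed. Without 1 array at a time, the counts ranged from 0 to 1 for IIAEK in wild type and for IIAEK over both genotypes, 0 to 2 for knockout against wild type on vehicle and on IIAEK, 0 to 10 over both treatments and 0 to 3 near Akp3, and the Akp3 difference from -3.50 to -2.78.

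Within slide 1 each wild-type group is 1 array, so no direction can be read for IIAEK in wild type. Lists that turned there were the following. For median changes, IIAEK in wild type gave triglyceride synthesis -0.0021, brush border 0.070, xenobiotic metabolism 0.10, proliferation -0.0025, distal small intestine -0.014 and exocrine pancreas -3.23. IIAEK in the knockout gave sugar transport 0.032, exocrine pancreas 0.24 and erythroid blood 0.099. Knockout against wild type on IIAEK gave interferon-stimulated genes 0.47, MHC class II 0.11, smooth muscle 0.11 and exocrine pancreas 0.13. The interaction gave brush border 0.21 and exocrine pancreas 3.44. IIAEK over both genotypes gave brush border 0.15, sugar transport 0.046, xenobiotic metabolism 0.14, interferon-stimulated genes -0.14, proliferation -0.019, T and NK cells 0.099, smooth muscle -0.091 and fibroblasts -0.057. Knockout against wild type over both treatments gave unfolded protein response 0.020, interferon-stimulated genes 0.32 and MHC class II 0.46. Within slide 2 IIAEK in the knockout is 1 array against 1, from which no direction can be read. Lists that turned there were adipose 1.05 for IIAEK in the knockout and proliferation 0.010 for knockout against wild type on vehicle. With array weights they were erythroid blood 0.20 for IIAEK in the knockout and T and NK cells -0.023 for IIAEK over both genotypes. Without the pancreas-high arrays they were exocrine pancreas -0.52 for IIAEK in wild type, exocrine pancreas 0.11 and erythroid blood 0.14 for IIAEK in the knockout, exocrine pancreas 0.49 for the interaction and interferon-stimulated genes -0.092 for IIAEK over both genotypes.

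Named genes that turned had, within slide 1, log2 changes of Akp3 -0.58, Abcg5 0.085, Npc1l1 0.26, Mttp 0.19 and Slc15a1 0.21 for IIAEK in wild type, Abcg5 0.14 and Abcg8 0.31 for IIAEK in the knockout, Akp3 0.35, Alpl 0.22 and Mttp -0.060 for the interaction, Akp3 -0.40, Alppl2 -0.088, Abcg5 0.11 and Slc15a1 0.32 for IIAEK over both genotypes. Within slide 2 these were Alpl -0.59, Abca1 -0.46 and Apob -0.016 for IIAEK in the knockout, Alpl -0.73 for knockout against wild type on IIAEK, Abcg5 -0.36 for the interaction, Alpi -0.056, Abcg8 -0.38 and Npc1l1 -0.11 for IIAEK over both genotypes, Alpl -0.081 for knockout against wild type over both treatments. With array weights they were Abcg5 0.027 for IIAEK in wild type, Abcg5 0.098 and Abcg8 0.081 for IIAEK in the knockout, Abcg5 0.062 and Npc1l1 -0.034 for IIAEK over both genotypes. Under quantile normalization they were Abcg5 0.030 and Mttp 0.024 for IIAEK in wild type, Apob -0.028 for IIAEK in the knockout, Alpl -0.020 for knockout against wild type on IIAEK, Abcg5 -0.17 for the interaction. With the mean of a gene's probes they were Abca1 -0.22 for IIAEK in the knockout. Without the pancreas-high arrays they were Abcg5 0.11, Npc1l1 0.0047 and Mttp 0.12 for IIAEK in wild type, Abcg8 0.026 for IIAEK in the knockout, Alpl 0.11, Abcg5 -0.16 and Soat2 -0.067 for the interaction, Abcg5 0.035 and Slc15a1 0.028 for IIAEK over both genotypes. None of these genes passed the threshold as reported. IIAEK in wild type within slide 1 and IIAEK in the knockout within slide 2 are 1 array against 1, so no direction can be read from those values.

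Without 1 array at a time, the log2 changes that turned in at least 1 fit ranged as follows. IIAEK in wild type gave exocrine pancreas -0.52 to 4.62, Abcg5 -0.22 to 0.11, Npc1l1 -0.28 to 0.052, Soat2 -0.067 to 0.26 and Mttp -0.21 to 0.12. IIAEK in the knockout gave exocrine pancreas -3.40 to 0.11, erythroid blood -1.72 to 0.14, Alpl -0.046 to 0.33, Abca1 -0.047 to 0.26, Abcg5 -0.19 to 0.11, Abcg8 -0.36 to 0.14, Npc1l1 -0.056 to 0.47, Apob -0.089 to 0.12 and Slc15a1 -0.11 to 0.94. Knockout against wild type on IIAEK gave interferon-stimulated genes -0.60 to 0.037 and Alpl -0.30 to 0.42. The interaction gave Abcg5 -0.19 to 0.19 and Soat2 -0.079 to 0.56. IIAEK over both genotypes gave interferon-stimulated genes -0.081 to 0.44, Abcg5 -0.15 to 0.016, Abcg8 -0.029 to 0.22, Npc1l1 -0.065 to 0.20 and Slc15a1 -0.53 to 0.050.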

Other observations

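All tests along chromosome 1 below were chosen after the result was seen, as were the count over all 200 splits and the split by slide, whereas the other splits of the arrays and the sex check were planned.

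Genes of the daily clock were not called as a list in any of the 7 comparisons. In wild type on IIAEK the clock repressor Nfil3 was at 1.73 (SE 0.41) and the nuclear receptor Nr1d2 at -1.21 (SE 0.34), both with a limma adjusted p of 0.369. The 16 clock genes had medians between -0.33 and 0.30 over the comparisons (camera adjusted p 0.305 to 0.968). The list test asks for a shared direction, so opposite moves such as those of Nfil3 and Nr1d2 can cancel. The missing call therefore does not show that the clock was alike. Hormone and transporter genes named by their list and not past the threshold in wild type on IIAEK were Ghrl, ghrelin, at -0.76, Slc34a3, a phosphate transporter, at -1.49 and Scarb1, the HDL receptor, at 1.05. The 20 enteroendocrine genes ranged from -0.19 to 0.20 in their medians (adjusted p 0.055 to 0.990), and the 15 genes of phosphate, calcium and iron transport from -0.025 to 0.20 (0.548 to 0.984). Spink4 of goblet cells was at 0.81 in the knockout on IIAEK, and the medians of the 15 goblet cell genes lay between -0.15 and 0.23 (0.093 to 0.928).

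Several lists that bear on cholesterol and bile acids were not called in any of the 7 comparisons. The 20 genes of sterol absorption, efflux and esterification had medians between -0.088 and 0.22 (camera adjusted p 0.440 to 0.968), 15 LXR targets between -0.45 and 0.23 (0.175 to 0.985), 10 genes of bile acids and FXR between -0.24 and 0.18 (0.090 to 0.916) and 23 PPARA targets between -0.17 and -0.015 (0.213 to 0.946). Apoe changed by -0.52 in the knockout on IIAEK, and Nr0b2, the FXR target SHP, differed by -0.91 between the genotypes on IIAEK, neither past the threshold. Intestinal alkaline phosphatase is known to detoxify bacterial lipopolysaccharide, and the 23 genes of lipopolysaccharide and NF-kappaB signalling had medians between -0.27 and 0.27 (0.057 to 0.925). Macrophages (17 genes, -0.16 to 0.15, adjusted p 0.070 to 0.802), mast cells (8 genes, -0.48 to 0.61, 0.110 to 0.968), eosinophils and neutrophils (10 genes, -0.036 to 0.18, 0.625 to 0.928), stem cells (10 genes, -0.12 to 0.22, 0.116 to 0.982) and the proximal small intestine (11 genes, -0.17 to 0.11, 0.404 to 0.928) were not called either.

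The labels give all mice as male. Xist lay below detection on all 12 arrays, between -7.07 and -8.17. Genes of the Y chromosome, each by its brightest probe, were well above background on all of them, whereas a dimmer probe of Kdm5d was not. Eif2s3y was lowest on wild-type IIAEK replicate 3, at 0.37 against 1.72 to 2.41 elsewhere, the array on which pancreas genes stood at 7.55.

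Splits of the same arrays into other groups bear on the counts. For the comparisons of 3 against 3 arrays there are only 10 splits, too few for a share under 0.05. A real count of 0 genes is reached by every split, so for the 6 comparisons with 0 genes the splits test nothing about chance. In wild type on IIAEK, where 0 genes passed, all 10 splits thus gave as many; the highest of the others gave 30, which points to a structure of the samples whose source was not tested. For lists, 3 splits gave at least the real 15, with 20 the highest of the others. In the knockout on IIAEK the values were 10 splits for 0 genes (highest other 0) and 7 for 11 lists (highest other 16). Between the genotypes on vehicle they were 10 for 0 genes (highest other 1) and 6 for 11 lists (highest other 17), and on IIAEK 10 for 0 genes (highest other 0) and 8 for 11 lists (highest other 19). Over both genotypes, all 100 splits gave as many genes as the 0 for IIAEK, with 145 the highest of the others, again a sign of structure whose source was not tested, and 18 gave at least the 17 lists (highest other 22). For the genotypes over both treatments, 64 of 100 gave at least 10 lists (highest other 24). Chance cannot be excluded for these 2 counts of lists. The median number of lists over the other splits was 11 for IIAEK in wild type and 12 for IIAEK in the knockout. Between the genotypes it was 12 on vehicle, 14 on IIAEK and 11 over both treatments. It was 11 for the interaction and 12 for IIAEK over both genotypes. Calls at the preset correlation are thus common under other groupings of the same arrays.

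The count of 1 gene between the genotypes over both treatments was set against splits of the arrays as well. Of the 100 drawn, 6 gave at least 1 gene (highest other 3), and of all 200 possible splits 8 did (4%, highest other 232). The 100 are a part of the 200, so 4% is the full share and the drawn share only an estimate of it. The splits count any gene that passes and so do not test Glrp1 itself. Whether chance can be excluded for Glrp1 is left open. The split with 232 genes is the one that follows the 2 slides, so slide is a structure of these samples; with slide as a block the count stayed at 1 and the change of Glrp1, IAP knockout against wild type over both treatments, was -2.30. The split by slide also gave at least as many genes and lists as the real one on vehicle (1 and 15) and on IIAEK (0 and 15), and 8 lists over both treatments. With slide as a block 7 of the 11 lists between the genotypes kept their call on vehicle, 7 of 11 on IIAEK and 6 of 10 over both treatments. Over all 200 splits for IIAEK over both genotypes, 33 gave at least 17 lists (highest other 23).

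Knockout differences gathered around Akp3 on chromosome 1. Fisher's exact test takes genes as independent, whereas all come from the same mice and neighbouring genes need not vary independently. Its p-values and intervals below therefore do not measure variation between mice. With Akp3 itself left out, 7 of 202 genes within 20 Mb of it had a limma p under 0.001, against 15 of 15586 elsewhere, an odds ratio of 37.2 (95% confidence interval 12.7 to 98.5, Fisher's exact p = 7.33e-09), while the list of genes near Akp3 fixed with the others had 1 of 52 (odds ratio 14.7, 0.348 to 94.8, Fisher's exact p = 0.0701), so DNA of another strain around the targeted gene is a candidate explanation. Within 60 Mb, a window chosen after it was seen to hold them, there were 11 such genes of 533, among them, chosen after their values were seen, Mogat1, an acyltransferase of triglyceride synthesis, at 1.52, Acadl, a fatty acid dehydrogenase, at -0.61 and Farp2 at 0.45. Chance differences of these mice were tested on 23 other genes within 60 Mb with p under 0.01 on vehicle. Of these, 18 (78.3%) had the same sign on IIAEK, against 112 of 354 (31.6%) elsewhere (exact binomial p = 0.0106 for the window, Fisher's exact p = 1.21e-05 between them). The share elsewhere lay below an even split of the signs, so it is no baseline for chance. The Fisher p against it therefore does not measure a departure from chance. The binomial test sets the window against an even split, but it takes neighbouring genes as independent. The share in the window also fell just short of the mark set for this test. Chance differences therefore stay open. Strain variants under single probes cannot be told apart from changed expression, since only 2 other probes were detected, of which 1 (that of Stk25) differed the same way.

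Ren2 was also named after its values were seen. This renin gene lies beside Ren1 on chromosome 1 in some mouse strains, is absent from C57BL/6 and is nearly identical in sequence to Ren1, so a probe for it can also bind Ren1. The knockout differed by 2.60 over both treatments, 2.30 on vehicle and 2.90 on IIAEK, none of which passed the threshold (limma adjusted p = 0.395, 0.423 and 0.648), with group means of -3.55 and -3.70 in wild type and -1.25 and -0.80 in the knockout. The strain of the mice is not given in the sources used here.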
